A study of Drosophila melanogaster with 4 samples.

How the data were processed

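Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on head nuclei of adult fruit flies (Drosophila melanogaster) of the wild-type Oregon-R strain, for histone H3 that carries acetylation at lysine 9 together with phosphorylation at serine 10 (H3K9acS10P), with what the labels call a new lot. Per the labels' protocols, flies were kept in population cages, heads were collected with sieves, and homogenised tissue was crosslinked with formaldehyde. Chromatin was released from the nuclei with detergent and sonication and was then immunoprecipitated. The series holds 2 ChIP samples and 2 input samples, and the labels assign 1 input to each ChIP sample. The labels call both ChIP samples replicates and do not say whether they came from separate fly collections, so the spread between them may be technical. The developmental stage is given only as mixed adult, and the sex of the flies is not given in the sources used here.

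Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase release r5 of the genome, per the file headers, and are 1-based with both ends included. Each ChIP sample has a deposited list of significantly enriched regions, called clusters here, with a start, an end and 1 score per cluster, and a further deposited list combines the replicates. The score is the authors' own value for each cluster. The program that called the clusters, the threshold, the scale of the score and the way in which the replicates were combined are not given in the sources used here. The deposited scores are all above 0 but may be on a log scale, so differences between scores within a list are given and no ratios, and agreement between the replicates is measured on ranks. No reads, counts or coverage per sample were analysed here, so the sequencing depth of each library is unknown and no limit from counting error can be set for a cluster. The inputs enter only through the authors' own calls, and no values of the inputs by themselves were analysed here. The narrowest cluster measured 1301 bp in both replicate lists and 1001 bp in the combined list. In the combined list 100% of starts and 100% of ends were even numbers, against 49.6% of starts in replicate 1 and 51.6% in replicate 2, so the positions of that list follow another grid than those of the replicate lists.

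The gene table at hand is of genome release 6, and its coordinates were not used with these r5 positions. Tests on genes that had been planned (genes with a cluster at the transcription start site, lists of genes, promoters, exons and introns) were therefore not run, and regions are named by arm, start and end. The rule for naming regions was fixed before the data were examined. It takes the 10 highest-scoring and the 10 widest clusters of the combined list that overlap a cluster in both replicates, and the 5 highest-scoring clusters of each replicate that overlap none in the other. A cluster counts as shared when at least 1 bp overlaps, unless stated otherwise.

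The overlap of the replicates was tested against 1000 circular shifts of replicate 2's clusters within each chromosome arm (one-sided). Agreement of scores was measured with Spearman's rho across overlapping pairs of clusters. Clusters are not independent replicates, so rho has a bootstrap interval over clusters (1000 draws, 95%) and no p-value. In place of the planned test on genes, the X was compared with the autosomal arms 2L, 2R, 3L and 3R in full windows of 500 kb by a two-sided permutation test with 100000 resamples. That test was chosen after the genome release was known, and its p-values measure the spread between windows, not between flies. In shared coverage, neighbouring windows resembled each other modestly on 2L and 3L (Pearson's r = 0.22 and 0.27). They did so little on X, 2R and 3R (0.10, 0.036 and 0.033). A rotation of the 236 windows along the joined arms, which keeps neighbours together, was therefore run as well. Benjamini-Hochberg adjustment covered the 4 measures compared per list (coverage, clusters per Mb, median width, median score). Chromosome 4 was placed among 9122 autosomal segments of its own length, taken every 10 kb. The centromere-proximal Mb of each large arm was compared with the rest of the arm, and so was the telomere-proximal Mb. Here the rest of the arm leaves out the Mb at either end. The comparisons used an exact sign-flip permutation test over 5 arms, which cannot give a two-sided p below 0.0625. Shares of clusters have exact (Clopper-Pearson) binomial intervals at 95%. Matching by width used groups of clusters with lower edges at 1000, 2000, 3000 and 4500 bp, the widest group left open.

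The tests were tried on simulated cluster lists with replicate 1's cluster widths (6248 clusters on the 5 large arms). The shift test gave p under 0.05 in 1 of 40 pairs of independent lists and in 20 of 20 pairs that shared 30% of their clusters. The window test gave p under 0.05 in 0 of 40 simulations without a difference, in 38 of 40 with X coverage raised 1.1-fold and in 40 of 40 with X coverage raised 1.3-fold. These simulated clusters were placed at random, without the uneven coverage along the arms or the resemblance of neighbouring windows on 2L and 3L. For the window test the number of clusters on each arm was fixed by the set coverage. Without a difference, X and autosomes were thus nearly equal by construction. The counts for the window test therefore give neither a false-positive rate nor a power that holds for these data. Windows named as richest or poorest, stretches without clusters and high-scoring combined clusters found in neither replicate were chosen after their values were seen. Alternatives covered the overlap criterion, a stricter score threshold, each replicate alone, clusters in either replicate, the combined list, window size and merging of neighbouring clusters. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.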

Results

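H3K9acS10P, a doubly modified form of histone H3 that combines a mark of active promoters (acetylated lysine 9) with a phosphorylated serine 10, was mapped by ChIP-seq in head nuclei of wild-type adult flies. The group of ChIP samples and the group of inputs had 2 samples each, and the labels assign an input of its own to each ChIP sample. The read depth of the samples is unknown. Positions are on FlyBase release r5, and scores are the authors' own, on a scale not given in the sources used here. The authors' lists held 6365 enriched clusters in replicate 1 and 6419 in replicate 2, and 8976 clusters in the list that combines both. Clusters covered 20.0 Mb in replicate 1 and 19.8 Mb in replicate 2, with those on the Het scaffolds and U included. On the assembled arms 2L, 2R, 3L, 3R, X and 4 they took up 16.5% and 16.3% of the sequence. The median cluster measured 2557 bp in replicate 1 and 2501 bp in replicate 2, with interquartile ranges of 1994 to 3701 bp and 1974 to 3604 bp. The median score was 0.82 and 0.79. Wider clusters scored higher, with Spearman's rho of 0.71 in replicate 1 and 0.72 in replicate 2 across clusters.

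The first question was whether the replicates found the same regions. They shared 16.8 Mb of enriched sequence out of 23.0 Mb enriched in either, an overlap of 73.2%. In replicate 1, 5533 of 6365 clusters (86.9%, exact 95% interval 86.1 to 87.7%) overlapped a cluster of replicate 2. In the other direction 5545 of 6419 did (86.4%, 85.5 to 87.2%). Replicate 2 covered 84.2% of the base pairs in replicate 1's clusters, against a mean of 16.5% and a highest value of 21.3% after circular shifts (p = 0.001, one-sided permutation, the smallest that 1000 shifts can give). The edges of clusters paired one to one lay a median of 126 bp apart at the start and 127 bp at the end. Scores of overlapping clusters ranked alike, with rho = 0.79 (95% bootstrap interval 0.77 to 0.80) over 5889 pairs. Clusters are not independent replicates. In the 4660 clusters paired one to one, rho was 0.84.

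**Figure D1:**
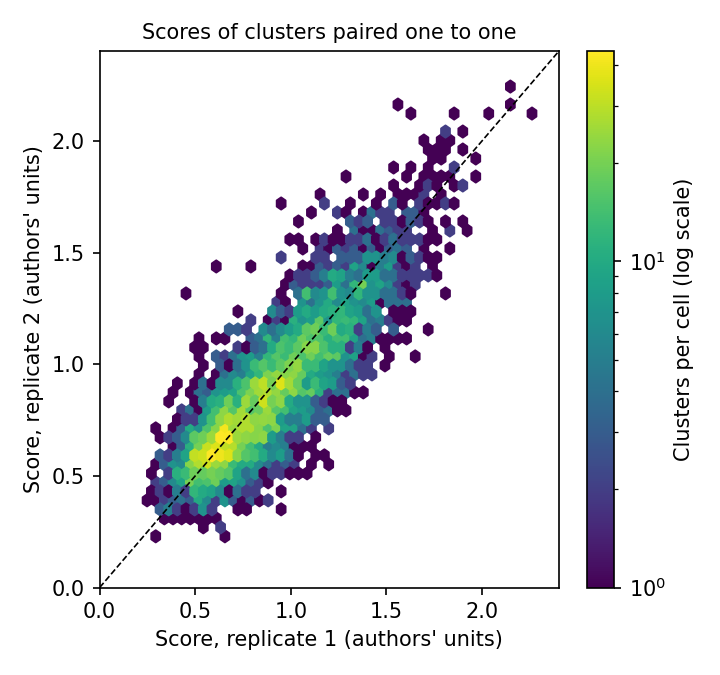
Scores of the 4660 clusters paired one to one, in the authors' units, with replicate 1 on the x axis and replicate 2 on the y axis; colour gives the number of clusters per cell on a log scale and the dashed line marks equal scores. Clusters with higher scores in replicate 1 had higher scores in replicate 2, with rho = 0.84 across these clusters.

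High-scoring clusters had a partner more often than low-scoring ones. Score rises with width, and a wider cluster meets the 1-bp rule more easily, so width may make up part of this difference. No chance level was computed for single clusters. With each list split by score into 4 groups of nearly equal size, 99.9% of replicate 1's and 99.8% of replicate 2's clusters in the highest group had a partner in the other list, against 67.5% and 69.2% in the lowest. The 832 clusters found only in replicate 1 had a median score of 0.59 and a median width of 1587 bp, where the shared ones had 0.87 and 2833 bp. The 874 found only in replicate 2 had 0.61 and 1600 bp, against 0.85 and 2783 bp. The strongest cluster found in replicate 2 alone lay on the unplaced scaffold U (7531121 to 7533121) and scored 2.25. That was the highest score in replicate 2's list. The combined cluster there scored 2.70, above the highest score of 2.18 among combined clusters found in both replicates. Next in replicate 2 came clusters on X at 17785758 to 17787586 (score 1.60) and at 19526866 to 19529457 (1.07), on chromosome 4 at 1312471 to 1314463 (1.04) and on X at 12475681 to 12477995 (1.04). In that order, these lay 874, 989, 6184 and 393 bp from the nearest cluster of replicate 1. The 5 strongest clusters of replicate 1 without a partner scored between 1.02 and 1.14. They lay on 2R at 11485599 to 11486987, on X at 11482824 to 11484748, at 6962656 to 6964968 and at 15329880 to 15332009, and on 3R at 23786796 to 23788796. Their distances to the nearest cluster of replicate 2 were, in that order, 11321, 374, 17162, 1283 and 1582 bp. The clusters at 374, 393, 874 and 989 bp thus lay nearest to a cluster of the other list. All of them were on X, where the median gap between clusters was 2.89 kb. No chance level was computed for these distances, so they do not show that both replicates found the same signal.

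The combined list took in nearly all of both replicate lists: 99.8% of replicate 1's clusters and 99.6% of replicate 2's clusters overlapped it. It was also larger. Of its 8976 clusters, 4972 (55.4%, exact 95% interval 54.4 to 56.4%) overlapped clusters of both replicates, 716 (7.98%) of replicate 1 only, 763 (8.50%) of replicate 2 only and 2525 (28.1%, 27.2 to 29.1%) of neither. Clusters present in both replicates had a median score of 0.81 and a median width of 3550 bp, while those in neither had 0.43 and 1313 bp. By base pairs, 58.3% of the combined list lay in both replicates and 21.3% in neither. A single combined cluster spanned at least 2 clusters of replicate 1 in 577 cases and of replicate 2 in 596 cases.

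The X chromosome carried broader enrichment than the autosomes in both replicates. Males have a single X whose output is raised by dosage compensation, and the kinase JIL-1, which phosphorylates histone H3 at serine 10 in interphase, is known to be enriched on it. Clusters covered 20.1% ± 0.25 (SD, n = 2) of X. The autosomal arms had 13.9% ± 0.17 on 2L, 17.7% ± 0.26 on 2R, 14.4% ± 0.23 on 3L and 16.3% ± 0.029 on 3R (SD, n = 2 each). X was thus above each of the 4 autosomal arms in both replicates, and its coverage was 1.29 ± 0.029 times (SD, n = 2) that of the 4 arms together. Sequence enriched in both replicates made up 16.9% of X and 13.2% of the autosomal arms, a ratio of 1.28. In 500-kb windows (44 on X, 192 on autosomes) that shared coverage differed with p = 0.00032 by the two-sided permutation test. When the windows were rotated along the joined arms, which keeps neighbours together, permutation gave p = 0.038 from 236 positions. The ratio of median window coverage, X over autosomes, was 1.33 (95% bootstrap interval over windows 1.08 to 1.65) in replicate 1 and 1.39 (1.17 to 1.66) in replicate 2.

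**Figure D2:**
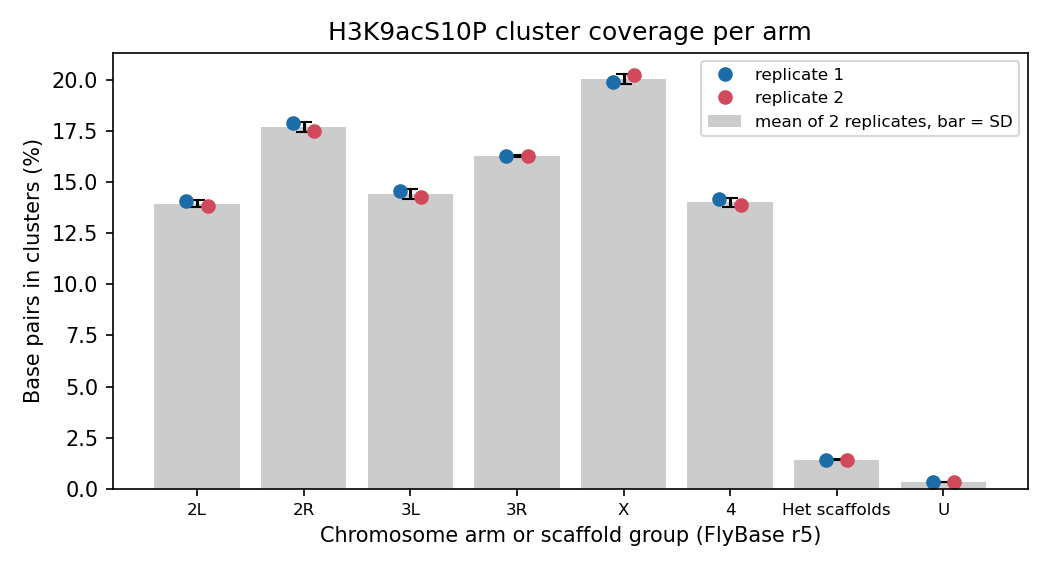
Percent of base pairs inside H3K9acS10P clusters for each chromosome arm, for the 6 Het scaffolds together and for scaffold U; grey bars are means of the 2 replicates with SD, and points are the replicates. X stands highest at 20.1%, the autosomal arms and chromosome 4 lie between 13.9% and 17.7%, and the Het scaffolds stand at 1.42%.

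The excess on X came with wider and higher-scoring clusters, and no difference in their number was detected. Clusters per Mb in windows averaged 55.6 on X and 52.1 on autosomes in replicate 1 (permutation p = 0.29, adjusted 0.29), and 52.0 and 53.4 in replicate 2 (p = 0.66, adjusted 0.66). Median width per window averaged 2834 bp on X and 2572 bp on autosomes in replicate 1 (permutation adjusted p = 0.00032). In replicate 2 the averages were 2993 and 2479 bp (permutation adjusted p = 2.7e-05). Median score per window averaged 0.11 higher on X in replicate 1 (permutation adjusted p = 0.00024). In replicate 2 it averaged 0.17 higher (permutation adjusted p = 2.7e-05, from a raw 2e-05, the smallest that 100000 resamples can give). Among clusters above the median score of their list, a filter that by itself keeps more of the higher-scoring X clusters, the difference in score was 0.018 (permutation p = 0.29) and the density on X was 1.45 times the autosomal one (permutation p = 2e-05), which restates the difference in score.

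The widest clusters were concentrated on X. Clusters of at least 10 kb made up 3.01% of X clusters and 0.498% of autosomal clusters in replicate 1, and 5.13% and 0.253% in replicate 2. X held 37 of the 62 clusters of that width in replicate 1 (59.7%, exact 95% interval 46.4 to 71.9%) and 59 of 72 in replicate 2 (81.9%, 71.1 to 90.02%), whereas it makes up 18.8% of the length of the 5 large arms. Once clusters within 1000 bp of each other were merged, the share on X was 47.2%, against a mean of 70.8% before. Of the 10 widest clusters of the combined list that were found in both replicates, 9 lay on X. The widest ran from 15593824 to 15644926 on X, 51.1 kb with a score of 1.13, and held 5 separate clusters in each replicate, the widest of them 27525 bp in replicate 1 and 31280 bp in replicate 2. It was followed on X by 38.8 kb from 2516368 to 2555196 (score 0.87), 34.8 kb from 1750964 to 1785740 (1.68), 32.7 kb from 15760540 to 15793280 (1.29) and 31.0 kb from 21204242 to 21235228 (1.06). The next 4 on X ran from 19371330 to 19396100, from 1962988 to 1987500, from 1787182 to 1811562 and from 512476 to 536726, and measured between 24.3 and 24.8 kb. The only autosomal member, on 3R from 5901944 to 5926000, was 1 unbroken cluster in each replicate, of 23963 bp in replicate 1 and 23056 bp in replicate 2.

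**Figure D3:**
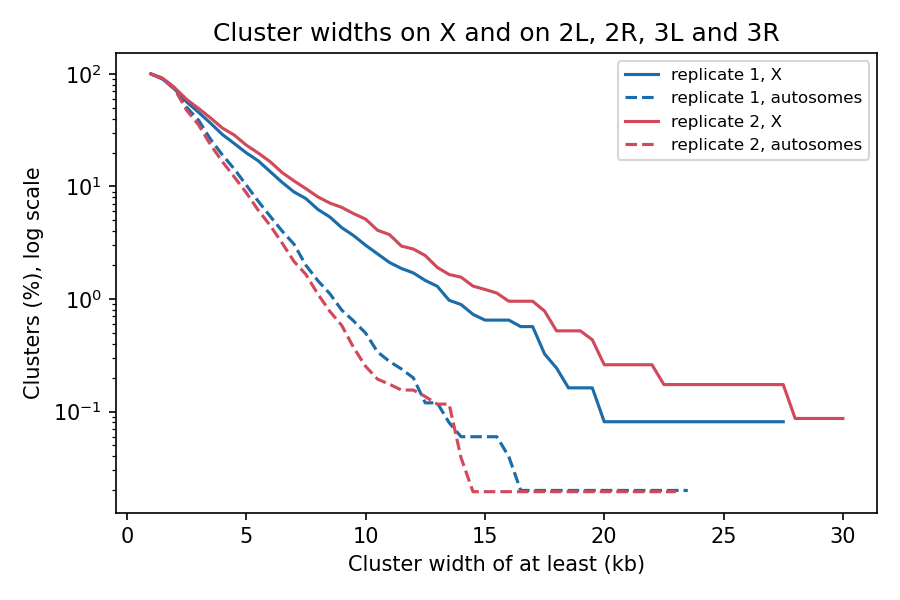
Percent of clusters (log axis) that are at least as wide as the value on the x axis in kb, for X (solid) and for 2L, 2R, 3L and 3R together (dashed) in each replicate. At 10 kb the X lines stand at 3.01% and 5.13% and the autosomal lines at 0.498% and 0.253%.

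Among the 10 highest-scoring clusters of the combined list that were present in both replicates, 4 were on 2L, 3 on 2R and 1 each on 3L, X and scaffold 3LHet, with none on 3R or chromosome 4; whether this differs from the arms' shares of all clusters was not tested. The first was a 4699-bp cluster on 2L at 8040254 to 8044952, which scored 2.18 in the combined list, 2.15 in replicate 1 and 2.24 in replicate 2. On 2R, the cluster at 12457000 to 12459670 scored 2.28 in replicate 1 and 2.13 in replicate 2, and the cluster at 16150514 to 16153644 scored 2.16 and 2.18. The cluster on 3LHet at 458626 to 461590 scored 1.84 and 2.14. The other members on 2L lay at 19007514 to 19010204, 22426594 to 22433294 and 10199480 to 10202880. The remaining members were on 3L at 4038540 to 4042146, on 2R at 20485432 to 20488898 and on X at 6902666 to 6909364, with combined scores of 1.87, 1.86 and 1.85. No annotation of genome release r5 was used here, so the genes in these regions are not named.

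Chromosome 4, a small autosome rich in heterochromatin proteins, was covered to 14.2% in replicate 1 and 13.9% in replicate 2, with 58 clusters in replicate 1 and 60 in replicate 2. Its coverage stood at percentile 35.7 of autosomal segments of equal length in replicate 1 and at percentile 33.1 in replicate 2 (two-sided share 0.713 and 0.662), so no difference was detected. The central 95% of those segments ran from 7.09 to 24.8% in replicate 1. Its median score was 0.97 in replicate 1 and 0.96 in replicate 2, at percentiles 97.7 and 98.2 of such segments. That placement did not hold after adjustment over 4 measures (adjusted two-sided share 0.18 and 0.14).

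Assembled heterochromatin held few clusters. The 6 Het scaffolds of release r5, which hold assembled sequence of pericentromeric regions and the Y, were covered to 1.42% in each replicate, 11.1-fold below the large autosomal arms in replicate 1 and 10.9-fold below in replicate 2; no test was run on this difference. Among them XHet stood highest, with 8.97% ± 0.14 (SD, n = 2). Scaffold U was covered to 0.327% ± 0.014 (SD, n = 2), and 0 clusters were listed on the 29.0 Mb of Uextra. How many reads could be placed uniquely on these repeat-rich scaffolds is unknown. The clusters that were found there, 59 in replicate 1 and 60 in replicate 2 on Het and U together, had median scores of 1.13 and 1.27, against 0.79 and 0.75 on the autosomal arms. Of these, 93.2% (exact 95% interval 83.5 to 98.1%) of replicate 1's clusters had a partner in replicate 2.

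Along the large arms, coverage fell off toward most centromeres. In replicate 1 the Mb nearest the centromere was covered to 6.29% on 2L, 6.57% on 2R, 2.19% on 3L and 7.94% on X. Each was less than its arm without the Mb at either end (14.1%, 18.5%, 14.8% and 20.4%). The exception was 3R, with 17.7% against 16.2%. How many reads could be placed uniquely near the centromeres is unknown too, so the drop may not come from the mark alone. Over 5 arms the mean difference was -8.66 points (SD 6.00) in replicate 1 and -8.71 points (SD 6.05) in replicate 2, with 4 of 5 arms lower (exact permutation p = 0.125, two-sided, in each replicate). The Mb nearest the telomere averaged 20.2% and 20.0%, against 16.8% and 16.7% in the rest of the arms, and was higher in 4 of 5 arms in replicate 1 and in 5 of 5 in replicate 2 (exact permutation p = 0.125 and 0.0625). With 5 arms, 0.0625 is the smallest p these tests can give. The richest and poorest windows were picked by their values. The richest 500-kb window was on X from 15.5 to 16 Mb, with 45.5% ± 1.06 (SD, n = 2), and the poorest was on 3L from 23.5 to 24 Mb, with 1.28% ± 0.038. Of the 9 windows with a mean above 30%, 5 were on X. Window coverage in the replicates rose and fell together, with Pearson's r = 0.98 and Spearman's rho = 0.98 across the 236 windows, which are not independent replicates.

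**Figure D4:**
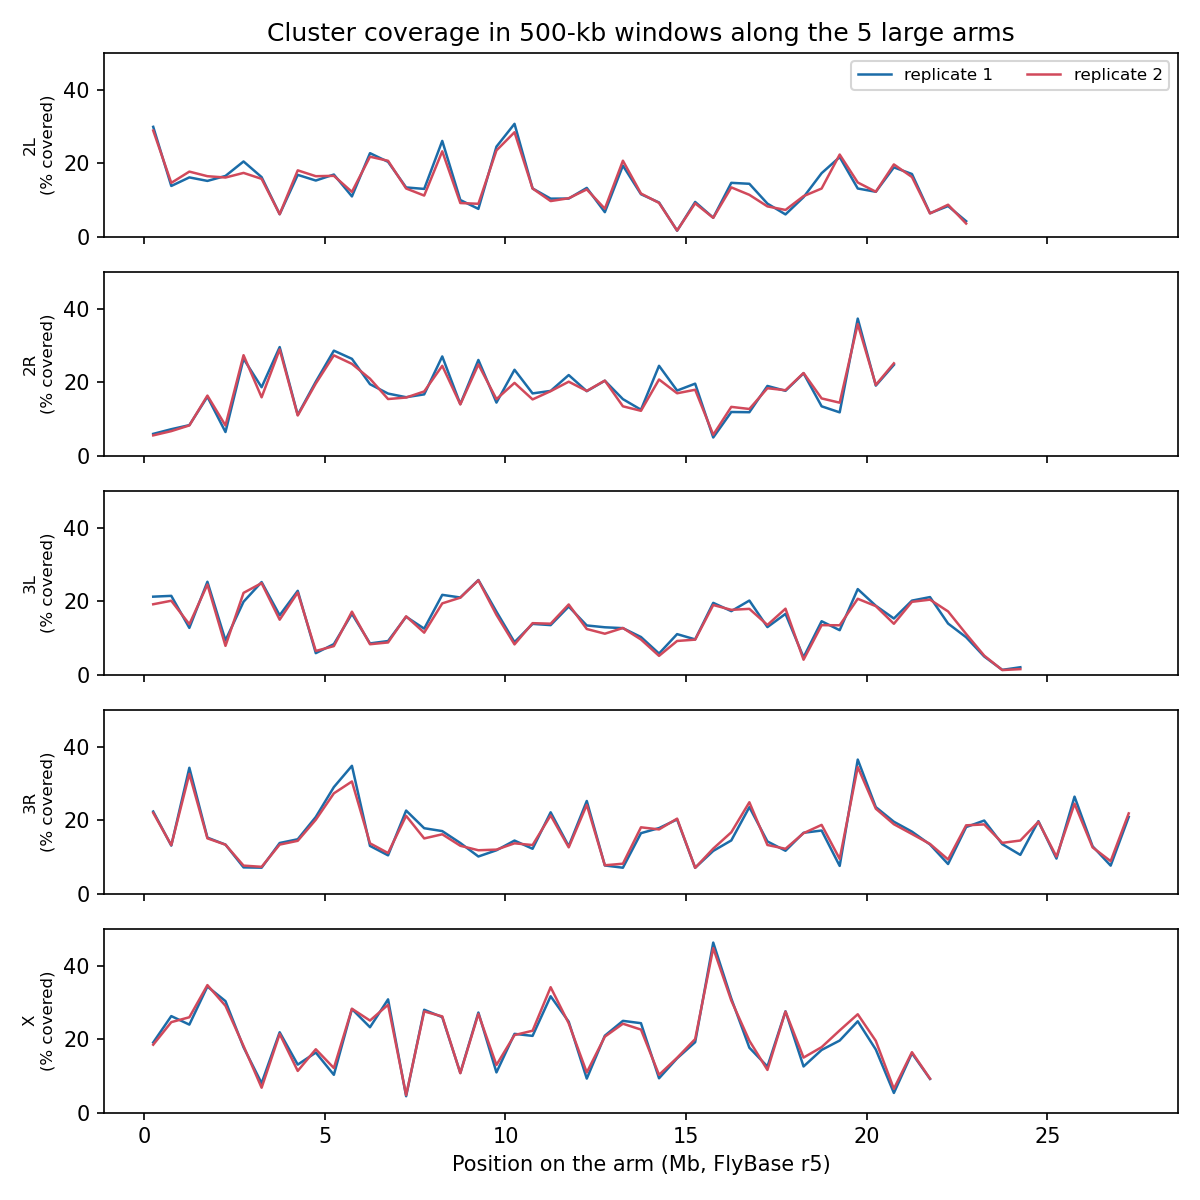
Percent of base pairs inside clusters in 500-kb windows (y axis) by position in Mb (x axis) along 2L, 2R, 3L, 3R and X, with a line for each replicate. The lines of the replicates nearly coincide, the highest window is on X at 15.5 to 16 Mb (45.5%), and coverage drops at the right ends of 2L, 3L and X and at the left end of 2R.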

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

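The window tests on X with their rotation and 1000-kb windows, the cluster density, width and score on X with their alternatives, the placement of chromosome 4, the tests of arm ends, the shares of wide clusters, the merging of clusters and the comparison of scores of named regions were chosen after the data were seen; the other alternatives were listed beforehand. No paired analysis was possible because the inputs that share replicate numbers with the ChIP samples have no values of their own here. Tests on genes, gene lists and genomic features were not run for lack of an annotation of release r5. The overlap of the replicates, the coverage and cluster width on X and chromosome 4's coverage stayed on the same side of the 0.05 threshold under every alternative run. The centromere-proximal difference ran from -13.7 to -6.18 points, in a test that cannot pass that threshold with 5 arms. The ratio of coverage on X to that on autosomes was 1.27 to 1.31 over the other alternatives and 1.80 among clusters above the median score, a filter that favours the higher-scoring X clusters and so is no support. Chromosome 4's ratio was 0.96 in shared sequence and went down to 0.78 in the combined list over the other alternatives. Among clusters above the median score, a filter that favours higher-scoring clusters, it was 1.26. None of these passed the threshold. Requiring clusters at least 1 kb wide removed none. Requiring 50% reciprocal overlap raised the score agreement to 0.845, and one-to-one pairs gave 0.842. The share of combined clusters found in the replicates was 56.9% among clusters above the median score, and with 1 replicate left out it was 63.4% to 63.9% (63.4% overlapped replicate 1 and 63.9% overlapped replicate 2). Among clusters above the median score, clusters per Mb on X rose to 1.45 times the autosomal value (permutation p = 2e-05) and the score difference shrank to 0.018 (p = 0.29), both set in part by the filter on score. The share of clusters of at least 10 kb on X was 70.8% on average and 47.2% once clusters within 1000 bp were merged. The causes of these shifts were not tested beyond what the filters themselves do. For the named regions, 24 of 40 replicate scores lay further from the combined score than 1 SD between the replicates. This says nothing about stability, since the highest score was taken where a region held several clusters of a replicate, the lists may not share a scale, and the depth behind each score is unknown.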

Other observations

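The tests here were chosen after the results were seen; of the test on the median width of merged clusters only the bound was set before its own result was seen. Long stretches without any cluster in either replicate stood out along the large arms. The longest, 404 kb, lay on 3R from 2486687 to 2891133, followed by 373 kb on 3L (23334438 to 23707171), 343 kb on X (21502350 to 21844934) and 337 kb on 3R (12478826 to 12816189). The clusters of the combined list covered 0.0025% of the first and 1.13% of the fourth. When the same number of clusters was placed at random, the longest gap on 3R had a median of 108 kb and never exceeded 190 kb in 1000 draws (permutation p = 0.001, the smallest possible, as on each of the 5 large arms). On 3R, 4 gaps were longer than any random one. The random draws ignored the uneven coverage along the arms described above, so these p-values speak only against even placement. The stretch on X lay inside the centromere-proximal Mb, and the one on 3L reached into it, where coverage was already low. On chromosome 4 the longest gap was 80.2 kb, against a random median of 81.8 kb, and no difference was detected (permutation p = 0.54).

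The replicates also differed slightly on X. Replicate 2 listed 6.50% fewer clusters than replicate 1 on X (1151 against 1231) but 1.74% more base pairs, while on the 4 autosomal arms it listed 2.61% more clusters and 1.49% fewer base pairs. With 1 value per replicate this was not tested.

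For the broader coverage on X, merging within 1000 bp was used to test splitting by short gaps as the cause of the higher median width. The ratio of medians rose from 1.11 to 1.24 in replicate 1 (95% interval 1.14 to 1.37) and from 1.22 to 1.27 in replicate 2. Clusters on X lay closer together, with a median gap of 2.89 kb against 4.59 to 5.48 kb on the autosomal arms. Merging can raise the ratio for that reason alone, so it cannot decide this explanation. A few heavily covered windows are argued against as the whole cause of the broader coverage. The ratio of median window coverage was 1.33 in replicate 1 (95% interval 1.08 to 1.65, with windows taken as independent) and 1.39 in replicate 2 (1.17 to 1.66). Without the 5 highest X windows the ratio of mean coverage was 1.17 (1.01 to 1.34) in replicate 1 and 1.21 (1.06 to 1.37) in replicate 2. Dropping windows from X alone lowers that ratio by construction. For the clusters of at least 10 kb, splitting by short gaps stays open as a part of the cause. Merging lowered the percent of them on X from 59.7% to 42.1% (exact 95% interval 35.9 to 48.4%) in replicate 1. In replicate 2 it fell from 81.9% to 52.3% (45.8 to 58.8%), where X makes up 18.8% of the arms. False enrichment from lower depth on the X stays open too, since at matched width the percent of clusters with a partner in the other replicate, X minus autosomes, was -1.47 points in each replicate, with 95% intervals (-3.42 to 0.47 and -3.36 to 0.43) that hold both 0 and small drops. Gene density on X, the sex of the flies and dosage compensation were not tested, so no biological explanation was tested.

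The combined list's 2525 clusters found in neither replicate may have more than 1 source. Its lower minimum width could account for the narrow ones: 92.8% of combined clusters under 1301 bp were in neither replicate, against 16.9% of wider ones. The other 1296 were themselves at least 1301 bp wide. A combined cluster can be wider than its replicate counterparts, as on 2L at 8040254 (4699 bp against 4647 and 4597 bp). The lower minimum width therefore stays open for those near that limit. Weak signal that passes only in the combined list also stays open for the 1296. Their median score differed by -0.403 from that of clusters in both replicates (95% interval -0.414 to -0.392), but being listed in neither replicate goes with a low score in any case, so this decides nothing. By score, 4 clusters found in neither stood above every cluster in both (3.91 on 2RHet, 3.26 on 2L, and 2.45 on both X and 3LHet, against 2.18; named after their scores were seen), of which 3 were narrower than 1301 bp; with the scale of the score unknown, this leaves the strength of their signal open.

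Median scores above that of the autosomal arms, on X, chromosome 4 and the Het and U scaffolds, were set against cluster width, which rises with score; on chromosome 4 the higher score itself did not hold after adjustment. At matched width the score difference from the autosomal arms was still 0.106 on X in replicate 1 (95% interval 0.087 to 0.122) and 0.139 in replicate 2. On the Het and U scaffolds it was 0.323 (0.202 to 0.455) and 0.425. On X it ran from 0.019 (3000 to 4499 bp) to 0.150 (1000 to 1999 bp) in the closed width groups of replicate 1, and from 0.069 to 0.144 in replicate 2. In the open group from 4500 bp it was 0.166 and 0.215, but X clusters there may still be wider. The intervals given here take the clusters of 1 list as independent, which they are not, so they may be too narrow. Width is argued against as the whole cause on X and these scaffolds only as far as such coarse groups match it. On chromosome 4 the matched difference was 0.0962 in replicate 1 (-0.025 to 0.152) and 0.127 in replicate 2 (0.027 to 0.198), and with 58 and 60 clusters both the difference and the part of width stay open. Reads shared among repeats may also raise scores on the scaffolds, which cluster lists cannot test.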
